A study of Cyanidioschyzon merolae strain 10D with 12 samples.

How the data were processed

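RNA was sequenced from 12 libraries of Cyanidioschyzon merolae 10D, 3 for each of 4 time points. Per the labels' protocols, batch cultures were grown at 30 °C under 90 µmol photons of light from an optical density of 0.7 at 5% CO2 for 24 h, moved to 0.04% CO2 for 24 h and moved back for a further 24 h. Libraries were made with a kit that does not keep strand and were read as paired ends of 100 bases. The groups were HC 0 h, LC 3 h, LC 24 h and HC 24 h recovery, and the labels describe their 3 members as biological triplicates. Replicate numbers come from the sample titles.

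The deposited table holds 4970 genes. Its estimated counts are RSEM-type expected counts in 1 column per library, and per the submitters' processing notes the tools were CASAVA 1.8, Bowtie2, RSEM and edgeR. The roles of these tools, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Of the cells of the count columns, 94.0% held whole numbers, and all were rounded to whole numbers before testing. The deposited TPM values, per the file headers 1 per library and 1 mean per group, follow from the counts and the deposited gene lengths and were recomputed to within 3.6e-06. The authors' log2 fold changes in the deposited table are those of the mean TPM plus 1 and were recomputed to within 4.2e-08. The authors' deposited q-values come with no stated test or adjustment. Gene length is given in the deposited table for all but 14 genes, which hold 0.92% of all counts and have no TPM. Tests used the counts only. Each column was matched to its sample by its name, with 0 columns of per-sample values left unmatched. The q-values in the authors' deposited table were under 0.05 for 652, 1152 and 147 genes at LC 3 h, LC 24 h and recovery, of which 647, 1152 and 134 were also called here.

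Gene identifiers are those of the table, and descriptions are those it gives for the best Arabidopsis match. Of the 4970 identifiers, 4738 were found in the RefSeq gene table of assembly ASM9120v1, which was used for names only. An Arabidopsis name is a similarity, not a measured function, and 327 described genes had a match with an E-value above 1e-05.

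Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 12 libraries entered 1 fit of 4 groups, with TMM scaling, the default expression filter, robust quasi-likelihood dispersion and the quasi-likelihood F test, adjusted by Benjamini-Hochberg within each of 5 comparisons and called at an adjusted p under 0.05. The filter kept 4865 genes and removed 105. Log2 CPM values used for principal components, correlations between libraries and list tests carry a prior count of 2. Log2 changes of genes are those of the fit at its default settings. The comparisons set LC 3 h, LC 24 h and recovery against HC 0 h, recovery against LC 24 h, and LC 24 h against LC 3 h. The correlation that shared HC 0 h libraries give was taken from 20 simulations of unchanged groups. Standard errors were derived as the absolute log2 change divided by the square root of its quasi-likelihood F statistic.

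Gene lists were fixed as word patterns on the descriptions. The 27 lists were inorganic carbon uptake, photorespiration, C4-type carboxylation, Calvin-Benson cycle, photosystems and plastid electron transport, phycobilisome and light harvesting, tetrapyrrole synthesis, nitrogen uptake and assimilation, glycolysis, tricarboxylic acid cycle, starch and compatible solutes, fatty acid and lipid synthesis, mitochondrial electron transport, ATP synthase, antioxidant defence, heat shock and chaperones, proteasome and ubiquitin, autophagy, cytosolic ribosome, ribosome biogenesis, aminoacyl-tRNA synthesis, DNA replication and cell division, histones, phosphate, sulfate and metal transport, plastid genome transcripts, mitochondrial genome transcripts, and structural RNA. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over 135 tests, and again with an estimated correlation. The same was done for 61 functional categories of the table with at least 10 tested members. Word patterns caught some members of another function, and these are named where they moved.

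Genes are named by a rule. For each comparison with HC 0 h it takes the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 4, groups that do not overlap (10% of genes by chance for 3 against 3) and a described function. For the other comparisons it takes 4 and 4. It adds all members of the carbon uptake, photorespiration, nitrogen and C4-type lists, up to 2 rises and 2 falls of each other list, and CMV013C, CMV014C, CMI270C, CMT416C, CMG019C and CMQ436C. The text names part of the 266 genes this gave.

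The design, the lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were relative-log-expression and upper-quartile scaling, no low-count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, a replicate block, a fit of the compared groups alone, organelle transcripts left out, a 2-fold threshold, other set tests, and each library of the compared groups left out in turn. Added after the data were seen were fits without the 14 genes that have no length, with counts thinned to the smallest library, without replicate 1 of every group, and for gene counts without each library of the groups not compared.

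The code was tested on simulated counts for LC 3 h against HC 0 h with 200 of 4865 genes changed. edgeR called 57.6% of those changed by 0.5 on the log2 scale, 95.5% at 1 and 97% at 2, and 0.15% of the 4665 unchanged genes. DESeq2 called 68.2%, 98.5%, 97% and 0.54%. Library totals differed 2.93-fold from lowest to highest. Counts of all replicate pairs differed by more than sampling noise, with chi-square over degrees of freedom of 5.2 to 192.5, so that none was counted as a single library.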

Results

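Transcript abundance was measured by RNA-seq in wild-type Cyanidioschyzon merolae 10D, a unicellular red alga that lives in hot acidic springs. It asked how transcript levels change when the CO2 in the aeration gas is lowered and then raised again. Cultures grown at 5% CO2 (high CO2, HC) were sampled at 0 h, after 3 h and after 24 h at 0.04% CO2 (low CO2, LC), and again after a 24 h recovery at high CO2. No library came from a culture kept at 5% CO2 up to the later time points. Every comparison therefore also differs in time in culture, whose part cannot be told apart from that of CO2. Each of the 4 time points had 3 libraries, which the labels describe as biological triplicates, giving 12 libraries of 4970 genes. The estimated read counts summed to 9671516 to 11367647 per library at HC 0 h and 9887990 to 12063878 at LC 3 h. They summed to 13366148 to 22881422 at LC 24 h and 24296460 to 28346661 after recovery. Values are read counts normalised to library size (CPM), given as mean ± SD with n = 3. Log2 changes are given ± standard error. Gene functions are those of the best Arabidopsis match listed with each gene.

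The LC 3 h and LC 24 h libraries separated from each other and from the high-CO2 libraries in the principal components. The first component held 50.5% of the variance and the second 27%. On the first component HC 0 h libraries lay at -27.54 to -23.41 and recovery libraries at -21.37 to -12.22, close but without overlap. Recovery replicate 1 lay at a root-mean-square log2 distance of 0.337 from the mean of the HC 0 h group. It lay at 0.35 from the mean of the other libraries of its own group. That mean rests on fewer libraries, which alone tends to raise the distance. Replicate 1 of the LC 24 h group correlated with the other replicates of its group at r = 0.962 and 0.953 across genes, while replicates 2 and 3 correlated at 0.996. In the LC 3 h group these values were 0.975 and 0.971 against 0.991, and after recovery 0.983 and 0.978 against 0.994. At HC 0 h they were 0.983 and 0.984 against 0.992. Genes are not independent replicates, so these values describe the libraries only. The biological coefficient of variation was 9.9% at HC 0 h, 15.9% at LC 3 h, 19.1% at LC 24 h and 12.9% after recovery.

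**Figure D1:**
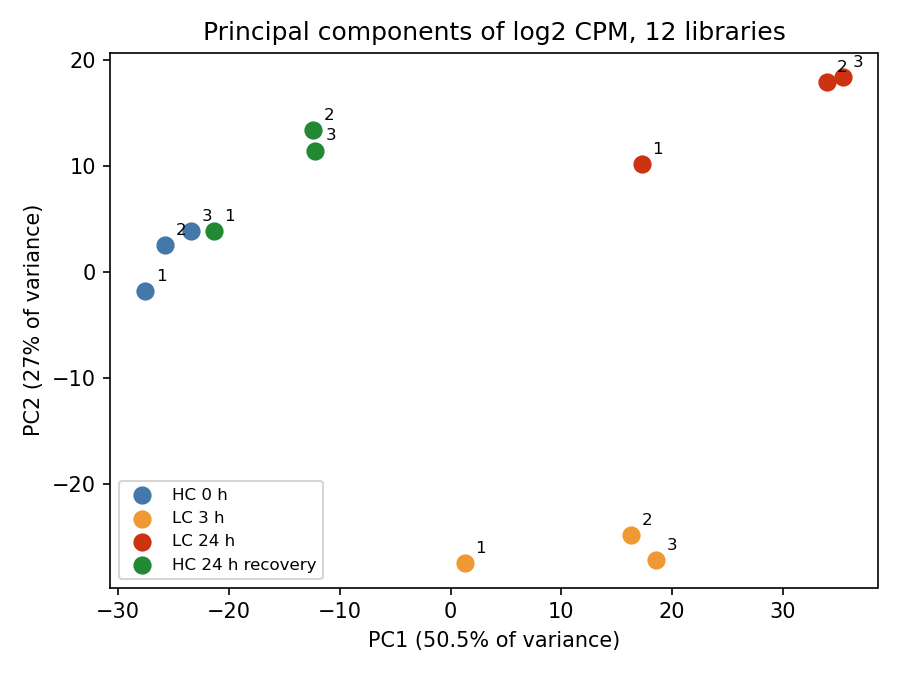
Principal component scores of log2 CPM for the 12 libraries, coloured by time point and numbered by replicate, with 50.5% of the variance on the horizontal axis and 27% on the vertical axis. Replicate 1 of LC 24 h lies nearer the high-CO2 libraries than the other LC 24 h replicates. Recovery replicate 1 lies nearer the HC 0 h libraries than the other recovery replicates do.

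Within 3 h at low CO2, single transcripts of inorganic carbon uptake and of photorespiration, the pathway that recycles the phosphoglycolate formed when Rubisco reacts with oxygen, rose to many times their starting level. CMT416C, matched to an alpha carbonic anhydrase, an enzyme class that interconverts CO2 and bicarbonate, went from 37.9 ± 2.58 to 2829 ± 450.4 CPM (log2 change 6.22 ± 0.18, edgeR quasi-likelihood adjusted p = 8.80e-09, Benjamini-Hochberg). The alanine:glyoxylate aminotransferase CMS429C rose from 163 ± 14 to 9618 ± 1530.2 CPM (log2 change 5.88 ± 0.22, edgeR adjusted p = 2.59e-08). Glycolate oxidase CMQ436C rose from 110.4 ± 18.1 to 2102 ± 395 CPM (log2 change 4.25 ± 0.23, edgeR adjusted p = 3.47e-07). The largest rise among the named genes was that of CML339C, matched to a YUCCA6-type flavin monooxygenase, from 11.4 ± 2.54 to 4154 ± 745 CPM (log2 change 8.50 ± 0.50, edgeR adjusted p = 5.49e-07).

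Of 16 tested photorespiration genes, 12 rose and 1 fell, the same genes being 12 higher and 2 lower adjusted over the list alone, with a median log2 change of 2.70. Camera gave the list an adjusted p of 3.03e-07 with a preset correlation and adjusted p = 0.464 with an estimated correlation. Beside the genes above, the risers included the serine hydroxymethyltransferase CMO142C at a log2 change of 4.27 ± 0.20, phosphoglycolate phosphatase CMR421C at 3.97 ± 0.20, the glycine decarboxylase P-protein CMR282C at 3.86 ± 0.22 and the aminomethyltransferase CMG086C at 3.81 ± 0.25. Catalase CMI050C rose by 3.58 ± 0.21, and the hydroxypyruvate reductases CMS425C and CMQ289C by 3.46 ± 0.23 and 1.53 ± 0.09. A further serine hydroxymethyltransferase, CMN332C, rose by 1.94 ± 0.15, and the glycine cleavage H protein CMF098C by 1.59 ± 0.16. The list also caught phosphoglycerate kinase CMJ305C, an enzyme of the Calvin cycle and glycolysis, which rose by 0.76 ± 0.11. The member that fell was the serine hydroxymethyltransferase CMI091C at -0.30 ± 0.09 (edgeR adjusted p = 0.0207). Its call ended without HC 0 h replicate 1 (0.0692), HC 0 h replicate 3 (0.0505), LC 3 h replicate 2 (0.0668) or LC 3 h replicate 3 (0.0779). The aminotransferase CMR117C, at -0.20 ± 0.08 and edgeR adjusted p = 0.0656, was not called lower, but was with DESeq2 (0.031), relative-log-expression scaling (0.0399), the replicate number as a block (0.0359) or without HC 0 h replicate 2 (0.0427).

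Of 7 inorganic carbon uptake genes, 5 rose and 1 fell, the counts being 5 and 1 also when adjusted over the list alone, with camera adjusted p = 0.0156 and adjusted p = 0.464 with an estimated correlation. The anion exchangers CMI004C and CMT006C, matched to the Arabidopsis boron transporter BOR4, rose by 2.10 ± 0.16 and 2.06 ± 0.17 on the log2 scale, and the anion exchanger CMR009C by 0.95 ± 0.18. CMI004C and CMT006C have near-identical descriptions, so reads may have been divided between them. A second alpha carbonic anhydrase, CMI270C, rose from 767 ± 99.3 to 1265 ± 94.4 CPM (log2 change 0.72 ± 0.21, edgeR adjusted p = 0.0157). That call ended without HC 0 h replicate 1 (0.0529), HC 0 h replicate 3 (0.0584) or LC 3 h replicate 2 (0.0506). The gamma carbonic anhydrase CMM052C was lower at -0.29 ± 0.08, with edgeR adjusted p = 0.0147, which became 0.0702 without LC 3 h replicate 2 and 0.0696 without LC 3 h replicate 3. The other gamma carbonic anhydrase, CMD023C, had a log2 change of 0.13 ± 0.09 and did not pass the test.

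**Figure D2:**
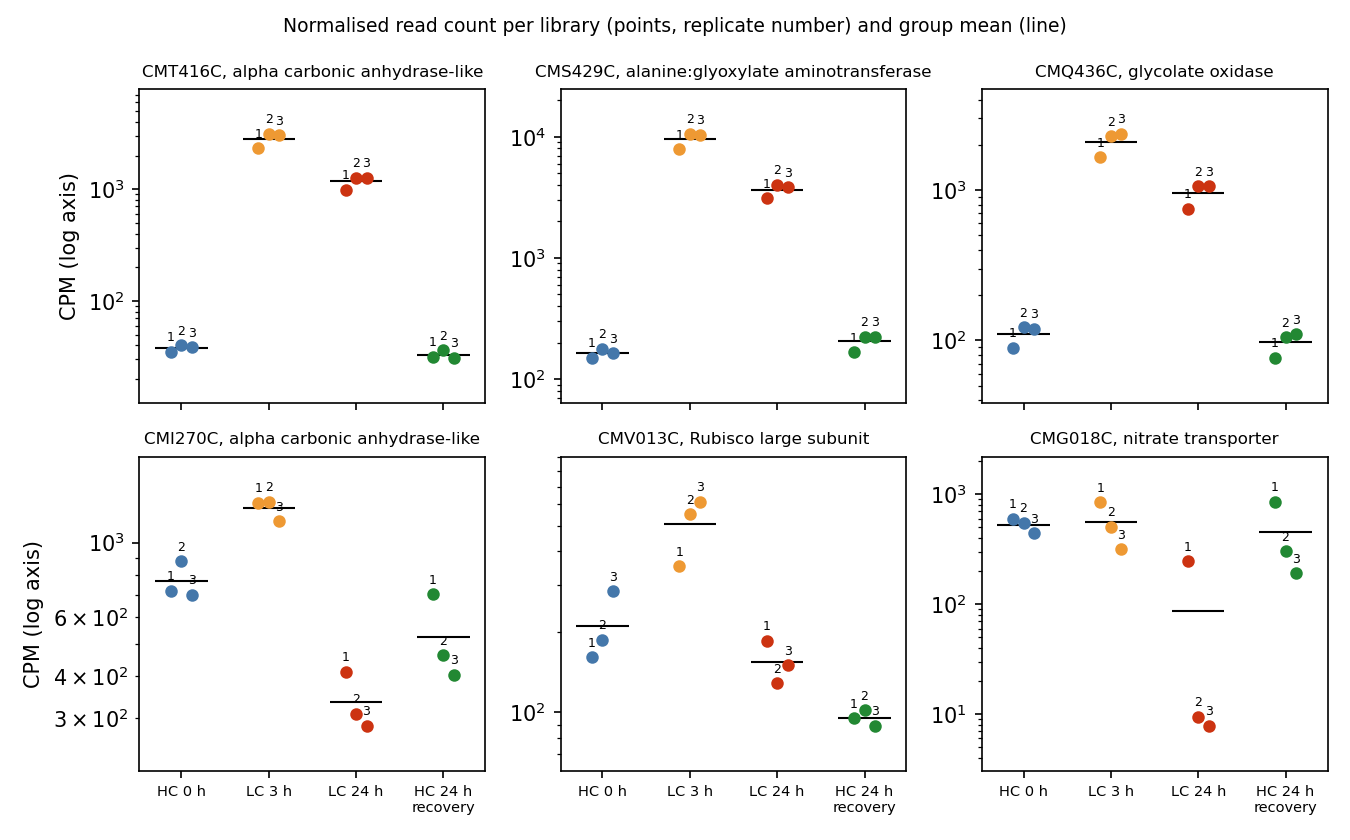
Normalised read count in CPM on a log axis for 6 genes, with 1 point per library, its replicate number above it, and the group mean as a line. CMT416C, CMS429C and CMQ436C are higher in all libraries of LC 3 h and LC 24 h than in those at high CO2, and CMG018C is higher in replicate 1 of LC 24 h than in replicates 2 and 3.

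Rubisco and glutamine synthetase transcripts also rose at LC 3 h. The Rubisco large subunit CMV013C rose from 211 ± 64.5 to 506 ± 136 CPM (log2 change 1.26 ± 0.24, edgeR adjusted p = 0.00162). The small subunit CMV014C rose from 63.2 ± 14.4 to 132 ± 25.2 CPM (log2 change 1.07 ± 0.20, edgeR adjusted p = 0.00151). Both are plastid genome transcripts in libraries selected for poly(A) tails, so carry-over of RNA without such tails is not excluded for them. Glutamine synthetase CMI233C, which assimilates ammonium, rose from 905 ± 103 to 6076 ± 1075 CPM (log2 change 2.75 ± 0.17, edgeR adjusted p = 8.43e-07). Of 11 nitrogen genes, 3 rose, the same number when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0954). The GATA factor CME102C rose by 0.63 ± 0.13 and the ammonium transporter CMK126C by 0.65 ± 0.11. Among 7 genes of C4-type carboxylation and decarboxylation, 3 rose and 4 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.886). Pyruvate phosphate dikinase CMF012C rose from 53.8 ± 2.51 to 1372 ± 545 CPM (log2 change 4.67 ± 0.34, edgeR adjusted p = 1.97e-06). The others were phosphoenolpyruvate carboxylase CME095C at 1.29 ± 0.18 and phosphoenolpyruvate carboxykinase CMN285C at 1.13 ± 0.08.

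Other named genes that rose at LC 3 h were the copper amine oxidase CMI002C at a log2 change of 5.09 ± 0.33, the AAA-type ATPase with ankyrin repeats CMT172C at 5.06 ± 0.27 and the haloacid dehalogenase-like hydrolase CMT388C at 4.60 ± 0.15. The adenylate kinase CMT384C rose by 4.32 ± 0.20. Glycolysis and gluconeogenesis genes were lower in 12 of 24 cases and higher in 7, 13 and 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.152). The beta subunit of pyrophosphate-dependent phosphofructokinase, CMH052C, fell from 343 ± 29.3 to 72.4 ± 34.9 CPM (log2 change -2.24 ± 0.40, edgeR adjusted p = 0.00117). The glyceraldehyde-3-phosphate dehydrogenase CMM167C changed by -1.67 ± 0.34 and cytosolic glucose-6-phosphate isomerase CMO124C by -1.47 ± 0.12. The 4 genes matched to L-lactate dehydrogenase, CMK006C, CMI306C, CMJ002C and CMA145C, changed by -2.23, -2.03, -1.96 and -1.60. Their separate values are uncertain because reads may be divided among near-identical copies. The alpha/beta-fold hydrolase CMT329C changed by -1.53 ± 0.29.

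Genes of the cytosolic ribosome fell together at LC 3 h. Of 57 tested, 40 fell and 17 did not pass the test, and 48 were lower adjusted over the list alone. The median log2 change was -0.47, and camera gave adjusted p = 5.96e-11 with the preset and adjusted p = 0.635 with an estimated correlation. Among 22 genes of starch and compatible solutes, 13 fell, with 14 lower and 1 higher adjusted over the list alone, with camera adjusted p = 2.67e-04 and adjusted p = 0.464 with an estimated correlation. The alpha-glucan phosphorylase CMD184C, which releases glucose 1-phosphate from starch, changed by -1.47 ± 0.24 and the disproportionating enzyme CMP352C by -1.27 ± 0.24. This list also held 3 genes matched to UPF1-like helicases, which act on RNA. Of 40 ribosome biogenesis genes, 15 fell and 3 rose, 16 and 3 adjusted over the list alone, with camera adjusted p = 0.0186 and adjusted p = 0.669 with an estimated correlation. The ribosome biogenesis call ended without LC 3 h replicate 1 (0.138).

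Of 149 tested plastid genome transcripts, 40 rose and 2 fell, 25 and 1 adjusted over the list alone, with a median log2 change of 0.79. Plastid transcripts had a camera adjusted p = 5.87e-05 and adjusted p = 0.775 with an estimated correlation. The photosystem II D1 protein gene CMV047C rose from 31.8 ± 9.52 to 214 ± 125 CPM (log2 change 2.75 ± 0.43, edgeR adjusted p = 4.84e-04). The 2 members that fell were the photosystem I subunit CMV236C at -0.67 ± 0.21 and CMV237C at -0.64 ± 0.22. Both calls ended without HC 0 h replicate 3 (0.0782 and 0.118), LC 3 h replicate 2 (0.0526 and 0.0977) or LC 3 h replicate 3 (0.0716 and 0.0905). That of CMV237C ended also without HC 0 h replicate 1 (0.0973) or LC 3 h replicate 1 (0.0525). Plastid transcripts held 0.511% to 0.65% of the counts of each library at HC 0 h and 0.612% to 0.812% at LC 3 h. They held 0.514% to 0.887% at LC 24 h and 0.549% to 0.644% after recovery, so the ranges of all groups overlap. The libraries were made with a kit that selects RNA with a poly(A) tail. The 14 genes without a length in the deposited table took 2.59%, 1.37% and 6.46% of the counts in the LC 3 h replicates 1 to 3, against 0.161% to 0.827% in the other libraries. All 10 of them that were tested rose at LC 3 h, with a median log2 change of 3.55.

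Over all tested genes, 1076 rose and 939 fell at LC 3 h, 2015 of 4865 or 41.4%, and 298 of the risers and 46 of the fallers changed at least 2-fold. With upper-quartile scaling the split was 861 higher and 1321 lower, so the share higher was 39.5% in place of 53.4%. Strand was not kept by the library kit, so reads from a gene and from an overlapping antisense transcript cannot be told apart in any comparison.

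After 24 h at low CO2 CMT416C and 11 of 16 photorespiration transcripts were above their starting level, and a larger part of the transcriptome had changed. CMT416C was at 1175 ± 159 CPM (log2 change from HC 0 h 4.95 ± 0.17, edgeR adjusted p = 3.25e-08). CMS429C was at 3654 ± 493 CPM (log2 change 4.48 ± 0.20, edgeR adjusted p = 9.41e-08) and CMQ436C at 958 ± 179 CPM (log2 change 3.12 ± 0.22, edgeR adjusted p = 1.07e-06). CML339C again had the largest rise among the named genes, to 3982 ± 583 CPM (log2 change 8.44 ± 0.50, edgeR adjusted p = 4.12e-07). Pyruvate phosphate dikinase CMF012C rose by 5.01 ± 0.34, the copper amine oxidase CMI002C by 4.60 ± 0.32 and CMT172C by 4.10 ± 0.26. The potassium channel-like CMP253C rose by 3.82 ± 0.19 and catalase CMI050C by 3.54 ± 0.21. In all, 1590 genes rose and 1475 fell, 3065 of 4865 or 63.0%, with 310 and 401 changed at least 2-fold.

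Of the 16 photorespiration genes, 11 were higher and 4 lower at LC 24 h, the same counts adjusted over the list alone. Their median log2 change was 1.69, with camera adjusted p = 0.0156 and adjusted p = 0.701 with an estimated correlation. Phosphoglycerate kinase CMJ305C was among those that fell, at -0.67 ± 0.11, and the H protein CMF098C was back near its starting level at -0.01 ± 0.16. The aminotransferase CMQ466C was lower at -0.61 ± 0.22 with edgeR adjusted p = 0.0318. This became 0.0549 without HC 0 h replicate 1, 0.117 without HC 0 h replicate 3, 0.0962 without LC 24 h replicate 1 and 0.0877 without LC 24 h replicate 2. A further aminotransferase, CMR117C, at -0.27 ± 0.08 and edgeR adjusted p = 0.0132, was not called without HC 0 h replicate 3 (0.0604). Carbon uptake genes were not called as a list at LC 24 h, with 4 of 7 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.316). The carbonic anhydrase CMI270C fell to 336 ± 67.7 CPM (log2 change -1.19 ± 0.21, edgeR adjusted p = 5.06e-04), and CMM052C changed by -0.87 ± 0.08. The anion exchanger CMR009C, at 0.56 ± 0.18 and edgeR adjusted p = 0.0169, was not called without HC 0 h replicate 1 (0.0618), LC 24 h replicate 2 (0.0548) or LC 24 h replicate 3 (0.0517).

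Cytosolic ribosomal protein transcripts were lower still at LC 24 h. Of 57 tested, 55 fell, also 55 adjusted over the list alone. Their median log2 change was -1.32, and camera gave adjusted p = 2.19e-20 with the preset and adjusted p = 0.464 with an estimated correlation. The small-subunit proteins CMS189C (RPS3a) and CMI202C (RPS15a) changed by -2.12 ± 0.14 and -2.07 ± 0.12, CMS189C going from 953 ± 50.7 to 219.7 ± 30.6 CPM. Aminoacyl-tRNA synthetases went down in 23 of 37 cases and up in 7, 23 and 8 adjusted over the list alone. Camera gave this list adjusted p = 0.0228, adjusted p = 0.669 with an estimated correlation and 0.058 without LC 24 h replicate 1. The glycyl-tRNA synthetase CMC037C, for example, changed by -1.68 ± 0.18.

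Central carbon metabolism was lower at LC 24 h in each of 3 lists. Of 24 glycolysis and gluconeogenesis genes, 16 fell and 4 rose, the same adjusted over the list alone. Their median log2 change was -0.67, with camera adjusted p = 0.008 and adjusted p = 0.388 with an estimated correlation. Phosphoglycerate mutase CMK188C fell from 502 ± 26.1 to 60.2 ± 23.8 CPM (log2 change -3.06 ± 0.24, edgeR adjusted p = 1.95e-06) and CMM167C changed by -2.95 ± 0.35. Of 22 starch and solute genes, 16 fell and 3 rose, the same adjusted over the list alone, with camera adjusted p = 0.0017 and adjusted p = 0.464 with an estimated correlation. CMD184C changed by -1.96 ± 0.24, and UDP-glucose pyrophosphorylase CMS159C, which makes UDP-glucose, fell from 141 ± 0.929 to 15.1 ± 11.1 CPM (log2 change -3.19 ± 0.40, edgeR adjusted p = 5.46e-05). Of 25 genes of the tricarboxylic acid cycle, 15 fell and 6 rose, 16 and 6 adjusted over the list alone. Camera gave these genes adjusted p = 0.0429, adjusted p = 0.516 with an estimated correlation, 0.0552 without HC 0 h replicate 3, 0.0755 without LC 24 h replicate 1 and 0.0595 with the replicate number as a block. The citrate synthase CMQ191C changed by -2.18 ± 0.10 and isocitrate dehydrogenase CMS272C by -2.04 ± 0.21, while the peroxisomal-type citrate synthase CMA040C rose by 1.14 ± 0.11.

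Replication genes, lower as a group, and plastid transcripts, higher as a group, were called at LC 24 h. Of 90 genes of DNA replication and cell division, 41 fell and 21 rose, 41 and 22 adjusted over the list alone. Their camera adjusted p was 0.0496, with adjusted p = 0.719 with an estimated correlation. It was 0.064 without HC 0 h replicate 1, 0.0709 without LC 24 h replicate 2 and 0.0772 without LC 24 h replicate 3. The replication clamp PCNA, CMS101C, fell from 529.8 ± 133 to 105 ± 9.27 CPM (log2 change -2.33 ± 0.29, edgeR adjusted p = 4.72e-05), and the ribonucleotide reductase CML050C changed by -2.06 ± 0.47. Of 149 plastid transcripts, 39 rose and 6 fell, 31 and 5 adjusted over the list alone. The plastid list had camera adjusted p = 0.0287, adjusted p = 0.843 with an estimated correlation, 0.269 without HC 0 h replicate 2, 0.0554 without LC 24 h replicate 2 and 0.259 without LC 24 h replicate 3. Other named genes that fell were the oxidoreductases CMR398C at -3.56 ± 0.24, CMD099C at -2.94 ± 0.18 and CMO306C at -2.68 ± 0.11. The translationally controlled tumor protein homologue CMQ113C changed by -3.00 ± 0.23 and glycerol-3-phosphate dehydrogenase CMD113C by -2.64 ± 0.41.

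Among 7 C4-type genes at LC 24 h, 3 rose and 4 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.541, median log2 change -0.57, mean 0.19). Phosphoenolpyruvate carboxykinase CMN285C rose by 0.59 ± 0.08, while the malate dehydrogenases CMP193C and CMT611C changed by -1.43 ± 0.10 and -1.97 ± 0.22, CMM229C by -0.79 ± 0.08 and NADP-malic enzyme CMJ051C by -0.57 ± 0.06. Phosphoenolpyruvate carboxylase CME095C, at 0.49 ± 0.18 and edgeR adjusted p = 0.0315, was not called without HC 0 h replicate 1 (0.11), HC 0 h replicate 3 (0.0625), LC 24 h replicate 2 (0.0844) or LC 24 h replicate 3 (0.0817). Of 20 genes of the Calvin-Benson cycle and Rubisco, 4 rose and 8 fell, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.785). The risers included CMF050C, matched to a Rubisco large subunit methyltransferase, at 2.52 ± 0.10, and CMK141C, described as related to phosphoribulokinase, at 2.15 ± 0.19, and the Rubisco small subunit CMV014C changed by -0.85 ± 0.20. Of 36 genes of the photosystems and plastid electron transport, 9 rose and 5 fell, 7 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.721). It also held the sulfite reductase-like gene CMG021C, which rose by 1.48 ± 0.25.

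Nitrate transcripts varied between the replicates at LC 24 h. The nitrate transporter CMG018C was at 246, 9.43 and 7.82 CPM in LC 24 h replicates 1 to 3, against 532 ± 80.1 CPM at HC 0 h (log2 change -2.59 ± 1.13, edgeR adjusted p = 0.0649). Without LC 24 h replicate 1 its change was -5.95 with edgeR adjusted p = 8.54e-05. DESeq2 gave it an adjusted p of 0.0344, and with the replicate number as a block its change was -3.85 with edgeR adjusted p = 0.00825. Nitrate reductase CMG019C was at 207, 9.57 and 4.17 CPM (log2 change -0.97 ± 1.06, edgeR adjusted p = 0.444). When LC 24 h replicate 1 was left out its change was -4.45 with edgeR adjusted p = 3.05e-04. Glutamine synthetase CMI233C remained higher at 1.24 ± 0.16, the ammonium transporter CMK126C at 0.39 ± 0.11 and the GATA factor CME102C at 1.00 ± 0.13. The nitrogen list as a whole had 4 higher and 1 lower of 11, the same adjusted over the list alone, and was not called (camera adjusted p = 0.573). The ammonium transporter CMT526C, at 0.75 ± 0.37 and edgeR adjusted p = 0.0968, was not among the 4, but with the replicate number as a block it was at 0.82 with edgeR adjusted p = 6.36e-04.

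Of the genes called at LC 3 h and LC 24 h, 762 were higher at both and 682 lower at both, 1444 in all. Independent lists of these sizes would share 351.7 and 284.7 genes. As both comparisons use the same 3 control libraries, part of the excess may come from them. In 20 simulated runs with unchanged groups, sharing these libraries gave the log2 changes a correlation of 0.417 to 0.605 across genes. No gene was called in both comparisons of any run, but with at most 2 genes called in either these runs could not show what sharing adds to the overlap of changed genes. A further 57 genes were higher at LC 3 h and lower at LC 24 h, and 42 were lower at LC 3 h and higher at LC 24 h, each relative to HC 0 h.

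Compared directly, LC 24 h and LC 3 h differed in the transcripts of Rubisco, photorespiration and ribosomes, which were lower at 24 h. The Rubisco large subunit CMV013C fell to 155 ± 28.9 CPM (log2 change from LC 3 h -1.71 ± 0.24, edgeR adjusted p = 2.50e-04). The small subunit CMV014C fell to 35.0 ± 7.70 CPM (log2 change -1.91 ± 0.20, edgeR adjusted p = 4.36e-05). A change in carry-over is not excluded for these plastid transcripts here either. The CONSTANS-like zinc finger CMR409C rose from 93.8 ± 14.6 to 387 ± 10.0 CPM (log2 change 2.05 ± 0.11, edgeR adjusted p = 1.36e-06). CMH127C, a weak match to B-box zinc fingers with an E-value of 0.02, rose by 2.87 ± 0.16. CMG003C, matched to a peroxisomal ubiquitin-conjugating enzyme, rose by 2.12 ± 0.49 and the weakly matched kelch-repeat gene CMP358C by 2.00 ± 0.31. The voltage-dependent anion channel CMO111C changed by -2.75 ± 0.30, CMS159C by -3.09 ± 0.40 and CMR398C by -2.92 ± 0.23. FtsZ2-1, CMO089C, a tubulin-like protein of organelle division, fell from 1321 ± 345 to 239 ± 94.5 CPM (log2 change -2.47 ± 0.28, edgeR adjusted p = 6.01e-05).

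Between the LC time points, 1152 genes rose and 1435 fell, 2587 of 4865, with 88 and 328 changed at least 2-fold. With upper-quartile scaling the split was 1422 higher and 1184 lower, so the share higher was 54.6% in place of 44.5%. In the fit of the compared groups alone it was 1160 higher and 997 lower, a share of 53.8%. All 10 tested genes without a length were lower at LC 24 h than at LC 3 h, with a median log2 change of -3.84. Of 16 photorespiration genes, 13 fell and 1 rose, the same adjusted over the list alone, with camera adjusted p = 7.93e-04 and adjusted p = 0.635 with an estimated correlation. Cytosolic ribosomal genes were lower in 51 of 57 cases, 52 adjusted over the list alone, with a median of -0.92, camera adjusted p = 1.24e-15 and adjusted p = 0.516 with an estimated correlation. Glycolysis genes fell in 15 of 24 cases and rose in 1, 16 and 2 adjusted over the list alone, with camera adjusted p = 0.0156 and adjusted p = 0.388 with an estimated correlation.

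Further lists were also called lower at LC 24 h than at LC 3 h, and the number of lists called was 7, or 11 without LC 24 h replicate 3. Of 7 C4-type genes, 6 fell, also 6 adjusted over the list alone, with camera adjusted p = 0.0287, adjusted p = 0.464 with an estimated correlation and 0.0584 with the replicate number as a block. These included phosphoenolpyruvate carboxylase CME095C at -0.80 ± 0.18 and the malate dehydrogenase CMP193C at -0.84 ± 0.10, and also CMM229C, a 3-isopropylmalate dehydrogenase of leucine synthesis, at -0.54 ± 0.08. Of 6 histone genes, 4 fell, 5 adjusted over the list alone. The histone list had a median of -1.07, camera adjusted p = 0.0248, adjusted p = 0.669 with an estimated correlation and 0.0594 without LC 3 h replicate 1. The histone H4 genes CMN166C and CMN169C had identical values, so reads cannot be assigned to either, and changed by -1.64 ± 0.26. Among 57 antioxidant genes, 27 fell and 5 rose, the same adjusted over the list alone. They had camera adjusted p = 0.0213, adjusted p = 0.516 with an estimated correlation and 0.0755 without LC 24 h replicate 1. Of 90 replication and cell division genes, 38 fell and 11 rose, the same adjusted over the list alone. Their list had camera adjusted p = 0.0209, adjusted p = 0.691 with an estimated correlation and 0.0581 without LC 3 h replicate 1.

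**Figure D3:**
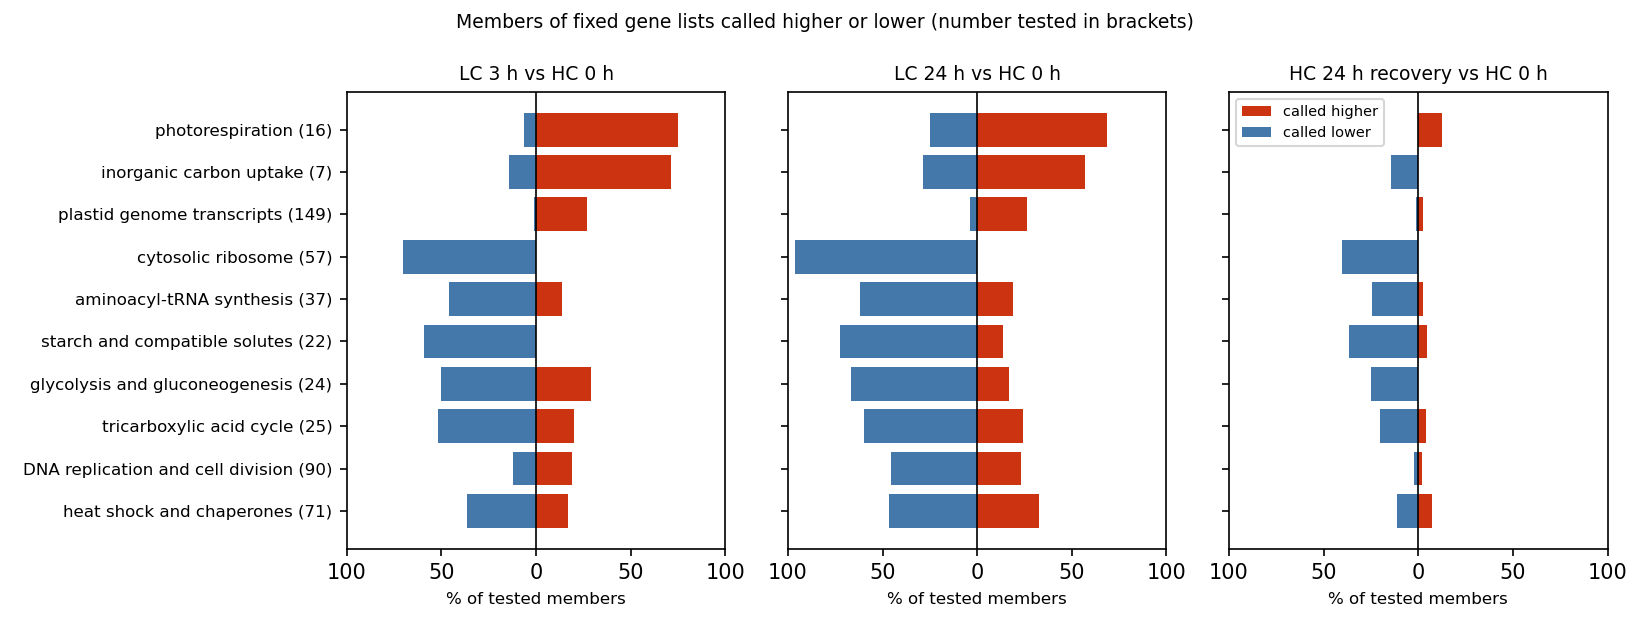
Share of the tested members of 10 gene lists, in percent, called higher (right) or lower (left) than at HC 0 h in each of 3 comparisons, with the number tested in brackets. Of 57 cytosolic ribosomal genes, 40 were lower at LC 3 h, 55 at LC 24 h and 23 after recovery.

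After 24 h back at high CO2 many transcripts had moved from their LC 24 h level. Relative to LC 24 h, CMT416C fell to 33.0 ± 2.92 CPM (log2 change -5.15 ± 0.17, edgeR adjusted p = 3.81e-08). Its log2 change from HC 0 h was then -0.20 ± 0.15 and did not pass the test. CML339C fell to 59.4 ± 30.5 CPM (log2 change -6.07 ± 0.44, edgeR adjusted p = 3.77e-06). The copper amine oxidase CMI002C changed by -4.62 ± 0.31 and the adenylate kinase CMT384C by -4.35 ± 0.20. UDP-glucose pyrophosphorylase CMS159C rose by 2.59 ± 0.39, CMM167C by 2.46 ± 0.34, the oxidoreductase CMR398C by 2.43 ± 0.23 and CMQ113C by 2.39 ± 0.22. In all, 1200 genes rose and 1213 fell between LC 24 h and recovery, 2413 of 4865, with 240 and 174 changed at least 2-fold.

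Of the 6 lists called lower at LC 24 h, 5 were called higher after recovery than at LC 24 h. The other, aminoacyl-tRNA synthesis, had 16 of 37 higher and 4 lower, the same adjusted over the list alone, and was not called (camera adjusted p = 0.0576). Of 57 cytosolic ribosomal genes, 54 rose, also 54 adjusted over the list alone, with camera adjusted p = 1.59e-20 and adjusted p = 0.464 with an estimated correlation. Of 22 starch and solute genes, 12 rose and 2 fell, 13 and 2 adjusted over the list alone, with camera adjusted p = 0.0156 and adjusted p = 0.516 with an estimated correlation. Glycolysis genes rose in 12 of 24 cases and fell in 4, 13 and 4 adjusted over the list alone, with camera adjusted p = 0.0186 and adjusted p = 0.388 with an estimated correlation. Among replication and cell division genes 37 rose and 16 fell, the same adjusted over the list alone, with camera adjusted p = 0.0261 and adjusted p = 0.691 with an estimated correlation. This call ended without recovery replicate 1 (0.0575). Tricarboxylic acid cycle genes rose in 14 of 25 cases and fell in 3, the same adjusted over the list alone, with camera adjusted p = 0.0287 and adjusted p = 0.489 with an estimated correlation. The cycle was not called without LC 24 h replicate 1 (0.0755). Photorespiration genes fell in 11 of 16 cases and rose in 3, the same adjusted over the list alone, with camera adjusted p = 0.00201 and adjusted p = 0.669 with an estimated correlation.

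Some transcripts differed from the start in the recovered cultures. The LHCA-like gene CMN234C, a chlorophyll-binding antenna protein of photosystem I, was at 9245 ± 2246 CPM after recovery against 3308 ± 121 CPM at HC 0 h (log2 change 1.48 ± 0.19, edgeR adjusted p = 0.00253). CMQ142C was higher by 1.37 ± 0.25. Of 4 genes in the light-harvesting list 3 rose, also 3 adjusted over the list alone, with camera adjusted p = 0.00638 and adjusted p = 0.464 with an estimated correlation. The remaining riser, CMN235C, named after its values were seen, changed by 0.92 ± 0.20. That call ended without HC 0 h replicate 1 (0.0565), recovery replicate 2 (0.0739) or recovery replicate 3 (0.0599). The list held no phycobiliprotein, and its other member was the photosystem II subunit CMV141C. Rubisco subunits CMV014C and CMV013C were lower than at the start, at -1.52 ± 0.21 (edgeR adjusted p = 0.00275) and -1.14 ± 0.24 (edgeR adjusted p = 0.0128). CMV013C was not called without recovery replicate 2 (0.0506) or recovery replicate 3 (0.0526). CML339C remained higher than at HC 0 h by 2.38 ± 0.39 (edgeR adjusted p = 0.00517) and the phosphatase CMN326C by 1.29 ± 0.25. The magnesium chelatase subunit CMB093C, an enzyme of chlorophyll synthesis, was higher by 1.09 ± 0.19.

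Lower than at the start after recovery were the ribosomal protein RPS30 gene CMT030C at -1.24 ± 0.16, the oxidoreductase CMR398C at -1.13 ± 0.21 and the organic anion or phosphate transporter CMP354C at -0.98 ± 0.15. Of 57 cytosolic ribosomal genes, 23 were lower, 34 adjusted over the list alone, with a median of -0.36, camera adjusted p = 2.47e-14 and adjusted p = 0.516 with an estimated correlation. Starch and solute genes were lower in 8 of 22 cases and higher in 1, 9 and 1 adjusted over the list alone, with camera adjusted p = 0.00183 and adjusted p = 0.464 with an estimated correlation. Glycolysis genes were lower in 6 of 24 cases, with 8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0249 and adjusted p = 0.388 with an estimated correlation. Aminoacyl-tRNA synthetases were lower in 9 of 37 cases and higher in 1, the same adjusted over the list alone. They had a camera adjusted p = 0.0228, adjusted p = 0.669 with an estimated correlation, 0.066 without HC 0 h replicate 3 and 0.103 without recovery replicate 1. The structural RNA list, whose 23 tested members are mostly enzymes that modify transfer and ribosomal RNA, had 2 lower, also 2 adjusted over the list alone, with camera adjusted p = 0.0156 and adjusted p = 0.388 with an estimated correlation. These were CMG043C, an aminoacyl-tRNA synthetase family member, at -0.38 ± 0.09 and the methyltransferase CMH261C at -0.29 ± 0.07. Neither was called without HC 0 h replicate 3 (0.0684 and 0.0502), recovery replicate 2 (0.0855 and 0.0811) or recovery replicate 3 (0.077 and 0.0541). CMG043C was also at 0.078 without HC 0 h replicate 1 and CMH261C at 0.0652 without HC 0 h replicate 2. Tetrapyrrole synthesis genes were higher in 7 of 23 cases and lower in 1, 7 and 2 adjusted over the list alone. Their list had a camera adjusted p = 0.0463, adjusted p = 0.728 with an estimated correlation, 0.101 without HC 0 h replicate 1, 0.0858 without recovery replicate 2 and 0.0774 without recovery replicate 3.

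Several single-gene calls after recovery lay near the threshold and ended with single libraries left out. In these fits the log2 change was 1.15 to 1.37 for CMV071C, 1.05 to 1.27 for CMD180C, -0.84 to -0.81 for CMP078C, -0.82 for CMT384C, -0.83 for CMD099C and 0.71 to 0.82 for CMI050C. The secA gene CMV071C (1.42 ± 0.35, edgeR adjusted p = 0.0237) was not called without HC 0 h replicate 2 (0.071), HC 0 h replicate 3 (0.0789) or recovery replicate 2 (0.0899). The GATA zinc finger CMD180C (1.22 ± 0.28, edgeR adjusted p = 0.0195) was not called without HC 0 h replicate 1 (0.0725), HC 0 h replicate 2 (0.0526), recovery replicate 2 (0.0857) or recovery replicate 3 (0.0712). The beta-galactosidase CMP078C (-0.89 ± 0.19, edgeR adjusted p = 0.0144) was not called without HC 0 h replicate 3 (0.0504), recovery replicate 2 (0.0774) or recovery replicate 3 (0.0635). Without recovery replicate 2 the adenylate kinase CMT384C (-0.85 ± 0.18, edgeR adjusted p = 0.0136) had adjusted p = 0.0623 and the oxidoreductase CMD099C (-0.83 ± 0.17, edgeR adjusted p = 0.0107) had 0.0571. Catalase CMI050C, still at 643 ± 113 CPM against 369.7 ± 38.3 CPM at the start, changed by 0.80 ± 0.19 (edgeR adjusted p = 0.0206). It was not called without HC 0 h replicate 1 (0.079), HC 0 h replicate 3 (0.0577), recovery replicate 2 (0.09) or recovery replicate 3 (0.0712).

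After recovery, 352 genes were higher and 332 lower than at HC 0 h, 684 of 4865 or 14.1%, and 22 and 5 of them changed at least 2-fold. This count was 304 without HC 0 h replicate 1, 368 without replicate 2 and 358 without replicate 3, and 913, 189 and 301 without recovery replicates 1, 2 and 3, and 1198 without LC 3 h replicate 1. It was 1251 with the replicate number as a block and 2340 without replicate 1 of every group. Of the 3065 genes called at LC 24 h, 2190 (71.5%) moved the opposite way between LC 24 h and recovery, and 614 (20%) were still called after recovery, 603 of them in the same direction. The first count comes from comparisons that share the LC 24 h libraries and the second from comparisons that share the HC 0 h libraries. Noise in shared libraries alone favours opposite signs in the first and like signs in the second, and its part was not tested. The count of 614 was 280, 336 and 326 without HC 0 h replicates 1, 2 and 3, 1076 without LC 3 h replicate 1, 813, 174 and 283 without recovery replicates 1, 2 and 3, and 1123 with the replicate number as a block. A further 70 genes were called after recovery but not at LC 24 h, a difference that was not itself tested.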

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

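The splits of the libraries reported here were planned, and no test in this part was chosen after its result was seen. The change from HC 0 h differed between LC 3 h and LC 24 h for 2587 genes, by the edgeR test of the difference itself. For 57 of these genes the transcript was called higher at LC 3 h and lower at LC 24 h, and for 42 lower and then higher. The named genes among them include 4 whose level rose by 3 h and then dropped below its start. The alpha carbonic anhydrase CMI270C was at 767 ± 99.3 CPM at HC 0 h, 1265 ± 94.4 at LC 3 h and 336 ± 67.7 at LC 24 h, a log2 difference of -1.91 between the LC time points, though its call at LC 3 h ended without HC 0 h replicate 1 (0.0529), HC 0 h replicate 3 (0.0584) or LC 3 h replicate 2 (0.0506). The Rubisco small subunit CMV014C, a plastid transcript for which carry-over of RNA without a poly(A) tail is not excluded, was at 63.2 ± 14.4, 132 ± 25.2 and 35.0 ± 7.70 CPM, with a difference of -1.91. Phosphoglycerate kinase CMJ305C was at 1647 ± 70.5, 2796 ± 292 and 1034 ± 8.25 CPM, with a difference of -1.43. The organelle division gene FtsZ2-1, CMO089C, was at 739.9 ± 128, 1321 ± 345 and 239 ± 94.5 CPM, with a difference of -2.47.

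Other named genes went the opposite way. CMH127C, weakly matched to B-box zinc fingers, was at 102 ± 12.4 CPM at HC 0 h, 63.2 ± 13.5 at LC 3 h and 463 ± 21.3 at LC 24 h, with a difference of 2.87 between the LC time points. The CONSTANS-like zinc finger CMR409C was at 124 ± 4.87, 93.8 ± 14.6 and 387 ± 10.0 CPM, with a difference of 2.05. The LHCA-like antenna gene CMN234C was at 3308 ± 121, 1810.5 ± 295 and 4603 ± 303 CPM, with a difference of 1.35. At LC 24 h against HC 0 h its edgeR adjusted p was 0.0469, and this call ended with any 1 of the 6 libraries left out. It was 0.11, 0.0855 and 0.104 without HC 0 h replicates 1 to 3 and 0.11, 0.0955 and 0.0721 without LC 24 h replicates 1 to 3. Relative-log-expression scaling gave 0.0545.

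The 6 libraries of a comparison can be divided into 2 groups of 3 in 10 ways, so the share of splits with as large a count cannot fall under 0.1. Each split was fitted by edgeR with all 12 libraries, and list p-values were adjusted within each comparison. Every other split has libraries of both time points in each of its groups, so a difference between the time points enters the spread. Any such difference, whatever its cause, leaves few gene calls there, so these counts do not test the calls. The real split of the genes was the only 1 of 10 with as large a count in each comparison. It gave 2015 calls at LC 3 h, 3065 at LC 24 h and 684 after recovery, each against at most 0 in any other split. It gave 2413 for recovery against LC 24 h, where the highest other was 1, and 2587 for LC 24 h against LC 3 h, where the highest other was 0. For gene lists other splits gave as many calls in 3 comparisons. The mixed splits keep part of the difference between the time points, so their list counts are not a chance level either. At LC 3 h 5 of the 10 splits called at least the 6 lists of the real one, with up to 9, and at LC 24 h 2 did, with 8 for the real split and 9 for the highest other. After recovery the real split, with 8 lists, was 1 of 10, the highest other being 6. For recovery against LC 24 h 4 splits called at least the 6 lists of the real one, with up to 8, and for LC 24 h against LC 3 h the real split, with 11, was 1 of 10, the highest other being 8.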

How the results depend on the processing

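Fits without the 14 genes that have no length, with thinned counts, without replicate 1 of every group and, for gene counts, without single libraries of groups not compared were chosen after the data were seen. No call was reversed in any gene count here, and the direction of each called gene or list named held in every setting run for it. The counts of changed genes stayed within 1.5 times the reported ones under both other scalings, both other filters, the fit of the compared groups alone and the fits without organelle transcripts, without the 14 genes (2033 at LC 3 h) and with thinned counts (1982). Requiring a 2-fold change left 344 genes at LC 3 h, 711 at LC 24 h, 27 after recovery, 414 for recovery against LC 24 h and 416 for LC 24 h against LC 3 h, by the construction of that threshold. The 684 genes called after recovery became 1071 with DESeq2, 2340 without replicate 1 of every group and 189 to 1198 with single libraries left out, the highest without LC 3 h replicate 1. The 614 genes of LC 24 h still called after recovery became 949 with DESeq2 and 174 to 1076 with single libraries left out. LC 3 h replicate 1 belongs to none of the groups that these counts compare. Leaving it out can move them only through the filter, scaling and spread of the shared fit. Which of these acted, and the cause of the other moves, was not tested. With any 1 of the 12 libraries left out the other counts ran from 1632 to 2363 at LC 3 h, 2643 to 3272 at LC 24 h, 1885 to 2669 for recovery against LC 24 h and 2123 to 2643 for LC 24 h against LC 3 h. For lists and named genes only libraries of the compared groups were left out. Camera with an estimated correlation called 0 lists in each comparison, against 6, 8, 7, 6 and 7 with the preset one. Over all 135 tests 11 had an unadjusted p under 0.05. fry's directional test called 17, 20, 10, 19 and 20 lists and its mixed test 25, 25, 20, 24 and 26, but neither compares a list with other genes. The lists called for LC 24 h against LC 3 h ran from 7 to 11 with single libraries left out, 11 without LC 24 h replicate 3. With a replicate block the genes called were 2400, 3331, 1251, 2812 and 2931, the genes still called after recovery 1123, and the lists 6, 7, 7, 6 and 7. The tricarboxylic acid cycle at LC 24 h (camera adjusted p = 0.0595) and the C4-type genes between the LC times (0.0584) were then no longer called. The Calvin-Benson cycle and Rubisco list gained a call, lower at LC 24 h than at LC 3 h (0.0285 against 0.0626 without the block). Same-numbered libraries deviated together in 15 of 18 pairs at a correlation over 0.1 (lowest -0.076, median 0.2955, highest 0.535), and in 15 of 18 the best match was the own number, a hint from the data and not from the design, so the numbers were not taken as pairs. Of 3123 recomputed values of named genes, 174 lost their call and 38 gained one. The alternatives for normalised values were not run, since the values are counts. Library totals differed 2.93-fold, and thinning to the smallest left 1982, 3016, 655, 2331 and 2512 genes called.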

Other observations

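The tests of plastid carry-over, of a constant difference of culture 1 and of the scaling of ribosomal protein genes were chosen after results were seen. Several gene lists had members that rose and members that fell and were not called at LC 24 h. Adjusted over the list alone their counts were the same as those given here, except that 16 ribosome biogenesis genes were lower. Of 71 heat shock and chaperone genes, 23 were higher and 33 lower at LC 24 h (camera adjusted p = 0.163). The chaperonin genes CMQ270C (HSP60) and CMF129C changed by -2.21 ± 0.17 and -2.41 ± 0.24 on the log2 scale, while CMI136C, matched to a P58IPK co-chaperone of the endoplasmic reticulum, rose by 1.87 ± 0.14. Of 54 fatty acid and lipid synthesis genes, 13 were higher and 21 lower (camera adjusted p = 0.358). Here acetyl-CoA carboxylase CMM188C rose by 1.89 ± 0.26 and the enoyl reductase CMT381C changed by -1.70 ± 0.10. Among 57 antioxidant genes, 20 were higher and 19 lower (camera adjusted p = 0.956), with the glyoxalase CMP184C up by 3.23 ± 0.24. Tetrapyrrole synthesis had 9 of 23 genes higher and 3 lower (camera adjusted p = 0.21), with the magnesium chelatase subunits CMB093C and CMV024C up by 2.16 ± 0.20 and 2.25 ± 0.26.

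In the mitochondrion, 9 of 44 electron transport genes were higher and 17 lower at LC 24 h (camera adjusted p = 0.311), and of 22 ATP synthase genes, which include vacuolar ATPase subunits, 3 were higher and 10 lower (camera adjusted p = 0.148). The mitochondrial ATP synthase beta chain CMH197C changed by -1.09 ± 0.14. Of 6 mitochondrial genome transcripts 2 were higher (camera adjusted p = 0.526). Of these, CMW011C, at a log2 change of 1.23 and edgeR adjusted p = 0.0209, was not called without HC 0 h replicate 1 (0.0613) or replicate 2 (0.0664). Nor was it called without LC 24 h replicate 2 (0.0671) or replicate 3 (0.0528). Mitochondrial genome transcripts held only 0.0012% to 0.0036% of the counts of each library, and carry-over of RNA without poly(A) tails is not excluded for them. Proteasome and ubiquitin genes were higher in 33 and lower in 22 of 85 cases (camera adjusted p = 0.644), ribosome biogenesis genes in 10 and 15 of 40 (camera adjusted p = 0.286) and genes of phosphate, sulfate and metal transport, mostly metal-binding enzymes, in 20 and 20 of 70 (camera adjusted p = 0.922). The autophagy pattern caught 4 genes, none of which acts in autophagy by its description, with 1 higher and 1 lower (camera adjusted p = 0.856). Of 305 tests of the functional categories of the table, camera called 26 with the preset correlation and 0 with an estimated one, where 22 had an unadjusted p under 0.05. Among these 26, regulation of transcription had 105 of 229 genes higher and 36 lower at LC 24 h (camera adjusted p = 0.0241, adjusted p = 0.556 with an estimated correlation).

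Replicate 1 of LC 24 h lay apart from its group, at a root-mean-square log2 distance of 0.53 from it against 0.259 and 0.328 for replicates 2 and 3. A constant difference of culture 1 stays open: the deviations of replicate 1 correlated across genes at 0.059 between HC 0 h and LC 24 h, but at 0.28 to 0.535 in the other 5 pairs of groups. RNA of a high-CO2 culture mixed into the library stays open: such a mixture needs the same fraction of the change in genes that rose and fell in replicates 2 and 3, and the median fractions were 0.783 of 300 risen and 0.832 of 465 fallen genes, differing by -0.05 (bootstrap interval -0.093 to 0.018). The quartiles of the fraction were 0.676 and 0.892 for risen genes and 0.481 and 0.994 for fallen genes. The fractions come from a single library, so the interval does not measure the spread between cultures. A weaker response of the culture of LC 24 h replicate 1, which may be biological, gives the same values and was not tested apart. The nitrate reductase CMG019C, at 207 CPM there against 9.57 and 4.17 in replicates 2 and 3 and 146 ± 29.6 at HC 0 h, is above each of the HC 0 h replicates, the highest of which was at 172 CPM, though not above recovery replicate 1 at 292 CPM.

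Cytosolic ribosomal protein transcripts fell at LC 24 h by a median log2 change of -1.32. Short transcripts are argued against as the whole cause, since 1132 other nuclear genes of the same lengths had a median of -0.05 and 4.9% of them were as low. Scaling of the libraries shifts all genes alike and so leaves the difference from those genes, -1.27, as it is, which argues against it for the fall relative to other genes. The other scalings moved the changes of all genes by a median of at most 0.026 there, so their list medians decide nothing. A lower level of these transcripts relative to others in the cells at low CO2 is then a hypothesis, from the same data in which the pattern was found. Other causes, such as a slower growth of the cultures, were not tested.

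Of 149 plastid genome transcripts, 40 were higher at LC 3 h and 39 at LC 24 h, 25 and 31 adjusted over the list alone, in libraries selected for poly(A) tails, where they can vary with the carry-over of RNA without such tails. The list was called at both times (camera adjusted p = 5.87e-05 and 0.0287) but not with an estimated correlation (0.775 and 0.843). The LC 24 h call ended without HC 0 h replicate 2 (0.269), LC 24 h replicate 2 (0.0554) or LC 24 h replicate 3 (0.259). At LC 24 h 6 plastid genes were called lower, among them the ribosomal protein CMV183C at -1.24 ± 0.28 and the RNA polymerase subunit CMV185C at -1.22 ± 0.22. At LC 3 h 2 were called lower, and both calls ended with some single libraries left out. These counts would speak against carry-over only if it raised all plastid transcripts alike, which was not tested. Carry-over thus cannot be told apart from a change in the cells at either time. The genes without a length took 2.59%, 1.37% and 6.46% of the counts in the LC 3 h replicates. Their share was 0.188% to 0.302% at LC 24 h, against 0.161% to 0.557% at HC 0 h. At LC 24 h 0 of the 10 tested were called higher and 0 lower, with a median log2 change of -0.332. These genes were not used in the test of carry-over.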
